A study of Mus musculus with 7 samples.

How the data were processed

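Messenger RNA of samples labelled as CD8+ T cells from the ascites of mouse models of peritoneal metastasis had been sequenced in 7 libraries, 4 untreated and 3 treated with propionate and butyrate. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, and stranded libraries were amplified by PCR. The authors deposited 1 table of TPM values with 149132 transcript rows, each carrying a gene symbol and no other identifier, and each library summing to the same total. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used and the genome build was mm39, without roles or versions, and the program that made the TPM values is not given in the sources used here. The symbols were used as given. The reference supplied was of an earlier build than mm39, so no genome coordinates are given.

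TPM divides each transcript's reads by its length and scales each library to the same total, so it carries no depth, and no counting interval or detection limit could be computed. A gene that takes a large share lowers all others in the same library. Mitochondrially encoded genes held 13.57% to 32.87% of TPM, highest in the third treated library, and 4 mitochondrial-like pseudogenes, chosen after their values were seen, held 8.15% to 18.4%, so reads shared between these copies are uncertain. Ribosomal protein genes held 8.31% to 17.2%.

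Columns were matched to samples by name. For 6 of the 7 the name gave the sample. The seventh column names the treated group with a number that no treated sample carries, so it was used as a treated library without a number, called the third treated library, and never paired. There were 0 other columns of values.

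TPM was summed over the transcripts of each symbol, giving 56422 symbols, and 1001 rows without a symbol, 0.307% to 0.618% of TPM per library, were left out. Genes with a TPM of at least 1 in at least 3 of the 7 libraries were tested (14967). Values were taken to log2(TPM + 1), so that fold changes are on that scale and understate the change of low genes, and the groups were compared in R 4.3.3 with limma 3.58.1, using an intensity trend in the variance and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. Before the data were examined, 32 gene lists were fixed, 11 of them markers of cells other than CD8+ T cells. Lists with at least 5 tested members, 31 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry as alternatives. Summed TPM per library of the 11 other-cell lists and of mitochondrially encoded and ribosomal protein genes was compared by a two-sided exact permutation test over all 35 splits of the 7 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over the 13 tests. A test of annotation terms had been planned for the case that the table carried such terms, which it does not, and was not run.

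Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes without overlap between the groups, leaving out model-number names and receptor segments. It adds up to 3 members of each list with the smallest p, and 23 genes fixed in advance. Genes named outside the rule were chosen after their values were seen. These are Krt8, Krt18, Wt1, Ubash3a, Ptprc, Cd4, Tnfsf14, Ikzf2, Bdh1, Sirt1, Kat6a, Slc2a3, Bcl2l11, Sesn3, Ifi44 and Bcl2l1, and those marked so where they are named. Among the genes the rule selects, 3 are not reported here singly; they stay in the fits, lists and counts.

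The model was tested on simulated data of 14967 genes built from the comparison of propionate and butyrate against control, with 40 genes changed at each size. It recovered 35% of genes raised by a log2 fold change of 1, 92.5% at 2 and 90% at 3, and 37.5% and 90% of those lowered by 1 and 2. It called 8 of 14767 unchanged genes and 0 of 20 unchanged lists. The simulated genes varied independently of each other, whereas the fixed lists had estimated inter-gene correlations of 0.20 to 0.92. The simulation therefore says nothing about false calls of lists whose genes vary together. Each simulated gene also had the same normal spread in both groups. In the data, T cell identity sums ran from 792 to 3359 in treated and from 161 to 285 in control libraries. The rates for single genes therefore hold for the simulated setting only. Alternatives changed the pseudocount, the filter, the scaling, the variance model, library weights, the replicate block, a macrophage covariate, the threshold and the set test, and left out each library in turn. Added after the data were seen were the T cell identity level as a covariate and the removal of control replicate 3 together with the third treated library. The labels carry the replicate numbers 1, 2 and 3 in both groups without saying that these pair the samples, and only 1 and 2 could be used as a block, since the third treated column could not be matched to a number.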

Results

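Messenger RNA was sequenced in samples labelled as CD8+ T cells, the cytotoxic lymphocytes that kill tumour cells, from the ascites of mouse models of peritoneal metastasis. In the control libraries Cd8a, a chain of the CD8 co-receptor, averaged 14.1 TPM, beside 5056 TPM of Apoe, a macrophage transcript, and 502 TPM of Wt1, a mesothelial gene. The comparison asked how gene expression in these samples differed after treatment with propionate and butyrate, short-chain fatty acids made by gut bacteria, in a series concerned with mannose and PD-1 blockade in ovarian cancer. There were 7 libraries, 4 from untreated controls and 3 from treated mice. The labels do not say whether each came from a separate animal, so p-values measure the spread between these samples, which may be technical. Expression was given as TPM, a length-corrected unit scaled to the same total in every library, so the sequencing depth was unknown. The number of genes at a TPM of at least 1 ranged from 13913 to 14949 per library. Across genes, which are not independent replicates, Spearman correlations were 0.964 to 0.982 between control libraries, 0.963 to 0.971 between treated libraries and 0.888 to 0.958 between the groups. The third treated library stood apart in its mitochondrially encoded share, 32.87% of TPM, against 13.57% to 18.23% in the other 6 libraries. The 4 mitochondrial-like pseudogenes held a further 18.38% of its TPM, against 8.15% to 10.59% in the other 6.

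Genes that define the T cell lineage were higher in the treated libraries. Cd8a and Cd8b1, the chains of the CD8 co-receptor, Cd3e, a signalling chain of the T cell receptor complex, Trbc1, a constant region of the receptor beta chain, and Lat, which carries the receptor signal, all rose. Cd8a averaged 14.1 ± 4.31 TPM (SD, n = 4) in control libraries and 136 ± 96.2 TPM (SD, n = 3) in treated libraries, a log2 fold change of 2.99 (SE 0.39). Its limma adjusted p with Benjamini-Hochberg adjustment was 0.000492. All 19 of the 19 tested T cell identity genes rose, by 2.18 (Ubash3a) to 3.17 (Trbc1) on the log2 scale, with a median of 2.81 or 7.02-fold. The same 19 rose when adjusted over the list alone. Their summed TPM was 224 ± 51.6 (SD, n = 4) in control and 1886 ± 1325 (SD, n = 3) in treated libraries. Every treated library, from 792 upwards, lay above every control library, up to 285 (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow). The list moved as a set in camera with a preset correlation (Benjamini-Hochberg adjusted p = 1.26e-39), with adjusted p = 0.227 with an estimated correlation. In the same libraries the summed TPM of tumour epithelium and mesothelium markers was 2633 ± 201 (SD, n = 4) in control and 1355 ± 419 (SD, n = 3) in treated libraries.

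**Figure D1:**
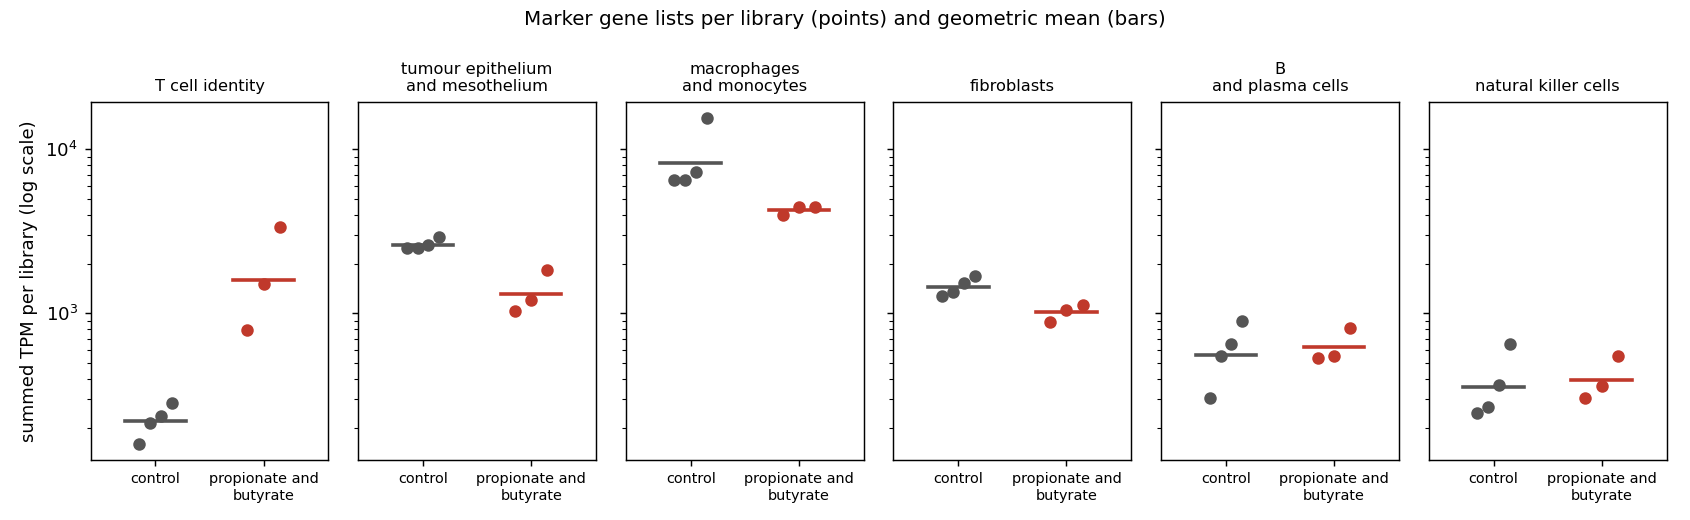
Summed TPM of marker gene lists on a log scale for T cells and 5 other cell types. Points are libraries (4 control, 3 propionate and butyrate) and bars are geometric means. T cell identity sums lie between 161 and 285 in controls and between 792 and 3359 in treated libraries, while epithelium and macrophage sums are lower in every treated library than in any control library.

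Cytotoxic and cytokine genes were higher alongside the T cell identity genes. Gzmb, Gzma and Gzmk, proteases of cytotoxic granules, Prf1, the pore-forming protein that delivers them, and Klrk1, an activating receptor, rose, as did Ifng, the main effector cytokine of these cells, and the chemokines Ccl5 and Xcl1. Gzmb went from 2.64 ± 1.22 TPM (SD, n = 4) to 33.8 ± 31.3 TPM (SD, n = 3), a log2 fold change of 2.96 (SE 0.43). Ifng went from 2.83 ± 0.994 TPM (SD, n = 4) to 27.1 ± 14.7 TPM (SD, n = 3), a log2 fold change of 2.79 (SE 0.31). The log2 fold changes of Gzma, Gzmk and Prf1 were 2.28, 2.74 and 2.23. Of 14 tested cytotoxic effector genes, 11 rose and 2 fell, with a median log2 fold change of 2.45. When adjusted over the list alone, 11 rose and 3 fell. Those that fell, Serpinb9 (-0.77) and Serpinb6b (-1.15), are serine protease inhibitors and are named after their values were seen. Of 13 tested cytokine and chemokine genes, 7 rose and 1, Csf1, the macrophage growth factor, fell (-0.62, named after its value was seen), with a median of 1.62. There were 8 higher and 1 lower when adjusted over the list alone. Tnf, a cytokine that macrophages also make, had a log2 fold change of 0.44 (limma, Benjamini-Hochberg adjusted p = 0.394). Il2 stayed below the expression filter at no more than 0.31 TPM in any library. Both lists moved as a set in camera with a preset correlation (Benjamini-Hochberg adjusted p = 4.87e-14 and 5.9e-11), with adjusted p = 0.227 for each with an estimated correlation. The cytokine and chemokine median was 0.99 without treated replicate 2, 0.64 with a pseudocount of 5 and 0.44 with no filter on low values. With median-of-ratios scaling Csf1 was not called (limma, Benjamini-Hochberg adjusted p = 0.0522) and Tnfsf14 rose, and robust variance estimation ended the call of Prf1 (0.0613). Summed epithelium and mesothelium markers were 0.501-fold the control level in the libraries where these genes were higher.

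Inhibitory receptors were higher in the same direction. Ctla4, a checkpoint receptor, rose from 1.18 ± 0.621 TPM (SD, n = 4) to 23.6 ± 20 TPM (SD, n = 3), a log2 fold change of 3.24 (SE 0.39), or 2.00 with a pseudocount of 5. Pdcd1, which encodes PD-1, went from 4.03 ± 1.63 TPM (SD, n = 4) to 33.3 ± 33.3 TPM (SD, n = 3), a log2 fold change of 2.41 (SE 0.46). The checkpoint receptors Lag3, Tigit and Havcr2 rose by 2.12, 2.38 and 1.6, and the transcription factors Tox and Eomes, which are linked to exhausted T cells, by 2.25 and 2.54. Of 23 tested genes of the exhaustion and inhibitory receptor list, 14 rose and 0 fell, with a median of 1.33. A total of 17 rose when adjusted over the list alone. The list moved as a set in camera with a preset correlation (Benjamini-Hochberg adjusted p = 3.38e-21), with adjusted p = 0.227 with an estimated correlation. With a pseudocount of 5 the median was 0.71 and Tox and Eomes were at 1.33 and 1.53, and with array weights Havcr2 and Lag3 were at 2.46 and 3.26. Robust variance estimation ended the calls of Tigit, Pdcd1 and Lag3 (limma, Benjamini-Hochberg adjusted p = 0.0536, 0.0849 and 0.0979), and Lag3 differed by 1.39 without treated replicate 2. In the same libraries the T cell identity genes had a median of 2.81, and summed epithelium and mesothelium markers were 0.501-fold the control level.

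Genes of naive and memory T cells were also higher in the treated libraries. Il7r, the interleukin 7 receptor chain that sustains memory cells, rose by 2.98, and Tcf7, the transcription factor of stem-like cells, rose by 2.21. Satb1 and Cd27 rose by 2.60 and 2.52. Of 23 tested members 15 rose and 0 fell (median 1.71), and 18 rose when adjusted over the list alone. Genes of terminal effector cells moved in the same direction. Klrc1, Klre1, Tbx21 and Klrg1 rose by 3.09, 2.42, 2.27 and 1.74. Of 17 members 8 rose and 0 fell (median 0.71), with 8 higher and 1 lower when adjusted over the list alone. In the tissue residency list, 5 of 14 members rose (Inpp4b, Xcl1 and Cd69, with Cxcr6 and Rgs1 named after their values were seen) and 1 fell (Isg20, named likewise, at -0.94). The median was 0.44, with 6 higher and 1 lower when adjusted over the list alone. In the activation and costimulation list, 7 of 20 rose, Cd28, Il2rb and Tnfrsf9 among them at 2.73, 2.46 and 2.14, and 0 fell (median 0.40). In all, 8 rose when adjusted over the list alone. Cd44, an adhesion receptor that many cell types carry, had a log2 fold change of 0.04 (limma, Benjamini-Hochberg adjusted p = 0.934). These 4 lists moved as sets in camera with a preset correlation (Benjamini-Hochberg adjusted p = 1.9e-22, 1.1e-10, 1.94e-05 and 2.14e-08). With an estimated correlation their adjusted p values were 0.227, 0.254, 0.474 and 0.387. Without treated replicate 2 the terminal effector, residency and activation medians were 0.29, 0.25 and 0.21, and without control replicate 3 the terminal effector and activation medians were 1.07 and 0.62. These 2 were 0.28 and 0.08 when a TPM of at least 5 was required, 1.33 and 0.73 with array weights and 1.13 and 0.63 with the macrophage covariate. A pseudocount of 5 gave medians of 1.10, 0.21 and 0.21 for the naive and memory, residency and activation lists, and residency was at 0.67 with no filter on low values. At that pseudocount Satb1, Klre1, Tbx21, Klrg1, Cd28 and Tnfrsf9 were at 1.62, 1.43, 1.15, 0.74, 1.59 and 1.33. Robust variance estimation ended the limma calls of Tcf7 and Il2rb (Benjamini-Hochberg adjusted p = 0.0679 and 0.0626), and median-of-ratios scaling that of Rgs1 (0.0901). The T cell identity genes had a median of 2.81 in the same libraries, where summed epithelium and macrophage markers were 0.501-fold and 0.517-fold the control level. Neither sum passed the exact permutation test (Benjamini-Hochberg adjusted p = 0.0619 each). The macrophage sum was mostly Apoe in control libraries, 5056 of 8948 TPM.

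**Figure D2:**
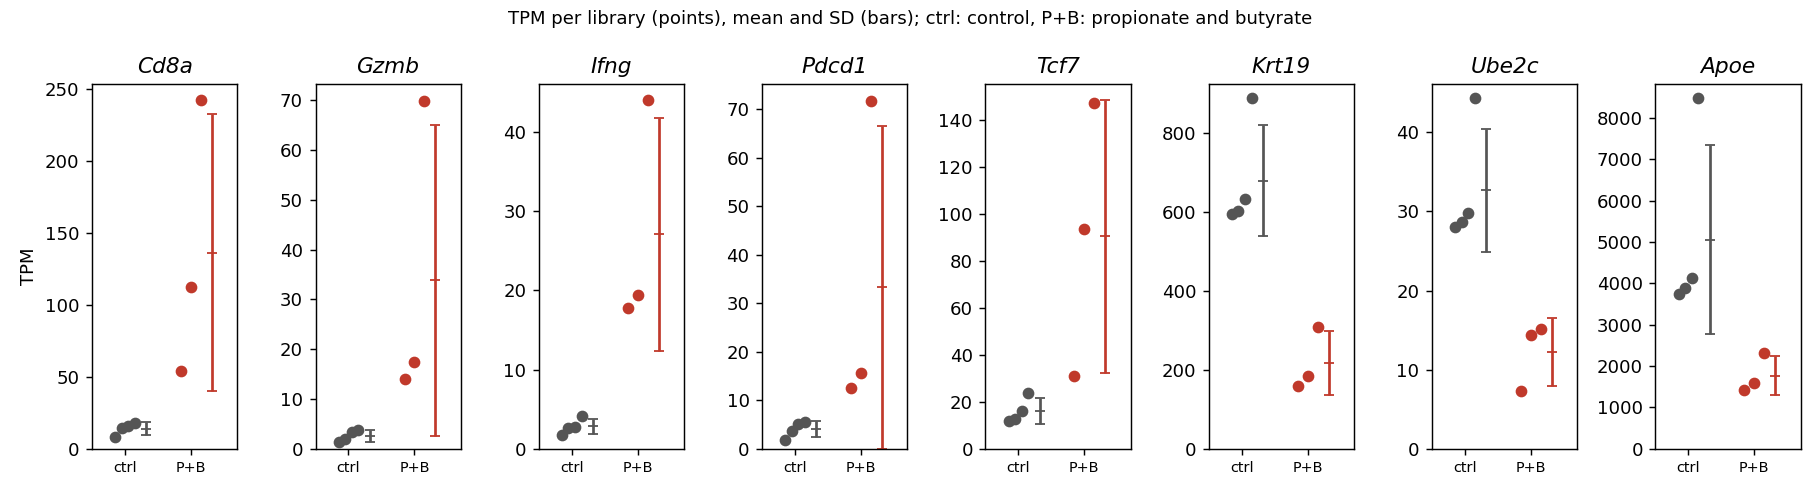
TPM of 8 named genes per library in control and propionate and butyrate groups. Points are libraries (4 control, 3 treated), the horizontal tick is the mean and the bar the SD, and each panel has its own linear axis. Cd8a, Gzmb, Ifng, Pdcd1 and Tcf7 lie higher in every treated library than in any control library, and Krt19, Ube2c and Apoe lie lower.

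Markers of other cell types differed between the groups, mostly downwards. Krt19, Krt8 and Krt18, keratins of epithelial and mesothelial cells, fell in the treated libraries. Krt19 fell from 680 ± 140 TPM (SD, n = 4) to 218 ± 80.4 TPM (SD, n = 3), a log2 fold change of -1.68 (SE 0.25). Cldn3, a tight junction protein, and Upk1b fell by 2.73 and 1.26. Of 15 tested genes of the tumour epithelium and mesothelium list, 9 fell and 0 rose (median -0.76), and 12 fell when adjusted over the list alone. Camera with a preset correlation gave this list a Benjamini-Hochberg adjusted p of 7.48e-05, with adjusted p = 0.477 with an estimated correlation. Of 13 fibroblast genes 7 fell, the matrix genes Col1a2 (-1.61) and Dcn among them, and 1 rose, Thy1, which is also a T cell identity gene (median -0.74). Among the 13, 9 fell and 1 rose when adjusted over the list alone. Camera gave an adjusted p of 0.0173, with adjusted p = 0.679 with an estimated correlation. Apoe, an abundant macrophage transcript, averaged 5056 ± 2280 TPM (SD, n = 4) in control and 1772 ± 478 TPM (SD, n = 3) in treated libraries, a log2 fold change of -1.45 (SE 0.32). Of 21 macrophage and monocyte genes 3 fell, Apoe and the Fc receptors Fcgr3 and Fcgr1 (the latter named after its value was seen), and 1 rose, Ly6c2, which memory CD8+ T cells also express (median -0.56). When adjusted over the list alone, 4 fell and 1 rose, and the camera adjusted p was 0.459. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt (the last named after its value was seen) made up the 4 of 5 erythroid genes that fell (median -2.02), and 4 fell when adjusted over the list alone. Camera gave an adjusted p of 0.0419, with adjusted p = 0.695 with an estimated correlation. They are near-identical copies in pairs, so the split of reads within a pair is uncertain. Of 4 endothelial genes, too few for a set test, Flt1, Esam and Plvap fell (median -0.83, 3 lower when adjusted over the list alone). Of 5 mast cell genes 1, Kit, fell (median -0.49, 1 lower when adjusted over the list alone, and camera adjusted p = 0.48). Camera no longer called the fibroblast list without treated replicate 2 (adjusted p = 0.129), or the erythroid list without treated replicate 1 or the third treated library (adjusted p = 0.154 and 0.35). The fibroblast call was also lost when a TPM of at least 5 was required or with the macrophage covariate (adjusted p = 0.275 and 0.0507), and the erythroid call with a pseudocount of 5, no filter, any of 3 other scalings, other variance models or array weights (adjusted p from 0.0529 to 0.633, medians from -2.63 to -0.41). With median-of-ratios scaling 1 macrophage gene fell, Apoe, and 1 rose, Fcgr3 and Fcgr1 having limma Benjamini-Hochberg adjusted p values of 0.192 and 0.163, and 2 erythroid genes fell, Hba-a2 and Hbb-bs. Robust variance estimation ended the limma calls of Hba-a1, Hba-a2 and Hbb-bs (Benjamini-Hochberg adjusted p = 0.165, 0.0842 and 0.101), and a pseudocount of 5 that of Plvap (0.0575), with Cldn3, Col1a2 and Flt1 at -1.41, -0.77 and -0.43. Leaving out the third treated library ended the limma calls of Apoe, Fcgr3, Dcn, Hba-a1, Hba-a2, Hbb-bs, Flt1, Esam and Plvap, with Benjamini-Hochberg adjusted p from 0.05 to 0.159, and those of Fcgr3, Flt1 and Esam were also lost without some of the other libraries, as was that of Plvap without treated replicate 2.

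Natural killer cell genes were higher, but 4 of the 6 that rose out of 10 tested, Gzma, Eomes, Xcl1 and Il2rb, are also T cell genes (median 1.53). In all, 7 rose when adjusted over the list alone. By camera the adjusted p was 2.63e-08, with adjusted p = 0.227 with an estimated correlation. The median was 0.73 with a pseudocount of 5, 0.79 with no filter and 2.37 when a TPM of at least 5 was required. The natural killer receptor genes Ncr1, Klrb1c and Klra8, named after their values were seen, stayed below the expression filter. They reached no more than 1.12, 2.96 and 2.1 TPM in any library and were not tested. Their means were nonetheless higher in treated libraries, at 0.96, 1.52 and 1.40 TPM against 0.39, 0.48 and 0.47 in control libraries. A larger share of natural killer cells therefore stays open. B and plasma cell genes had a median of 0.30, and 1 of 18, Sdc1, a proteoglycan of plasma and epithelial cells, fell, with the same number when adjusted over the list alone. The camera adjusted p was 0.0016, with adjusted p = 0.695 with an estimated correlation. That call was lost without control replicate 2 (median 0.04, adjusted p = 0.155) and without the third treated library (median 0.32, adjusted p = 0.132), and the median was 0.49, 0.45 and 0.18 without control replicates 3 and 4 and treated replicate 2. It was 0.19 with a pseudocount of 5, 0.53 with the macrophage covariate and 0.54 with median-of-ratios scaling, where Ebf1 also rose. In the CD4 and regulatory T cell list, 1 of 7 rose, Tnfrsf18, and 1 fell, Capg (median 0.47). When adjusted over the list alone, 1 rose and 2 fell, and the camera adjusted p was 0.247 (0.00901 with no filter). With median-of-ratios scaling Ikzf2 rose as well and Capg was not called (limma, Benjamini-Hochberg adjusted p = 0.067). Of 15 dendritic cell and MHC class II genes 1 rose, Siglech (median -0.31, and 0 when adjusted over the list alone). The camera adjusted p was 0.47 with the direction up, opposite to the median. Of 7 neutrophil genes 0 passed by either adjustment (median -0.26, and camera adjusted p = 0.98, also with the direction up, against a median of 0.31 and adjusted p = 0.0254 with the macrophage covariate). Tnfrsf18 and Siglech lost their calls without any of several libraries, at 0.65 and 0.63 without treated replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.146 and 0.172).

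In sums of TPM per library, macrophage and monocyte markers were at 8948 ± 4395 (SD, n = 4) in control and 4302 ± 280 (SD, n = 3) in treated libraries. Each of 6 sums, those of macrophages, epithelium and mesothelium, fibroblasts, endothelium, mast cells and CD4 and regulatory T cells, had its 3 treated values below its 4 control values, at 0.517, 0.501, 0.700, 0.648, 0.576 and 0.688 times the control geometric mean. The direction of the last turned to 0.18 on the log2 scale with the mean of log2(TPM + 1), its list having a median of 0.47, and Capg made up 135 of its 223 TPM in control libraries. Without the highest gene of each sum the log2 differences of macrophages, fibroblasts, endothelium and CD4 and regulatory T cells went from -0.95, -0.52, -0.63 and -0.54 to -0.50, -0.18, -0.15 and -0.13. The two-sided exact permutation p was 0.0286 for each, the smallest possible, and 0.0619 after Benjamini-Hochberg adjustment over 13 sums, so 0 of the 13 passed. The same test gave adjusted values of 0.106 for erythroid cells, 0.279 for dendritic cells, 0.844 for natural killer cells, 0.898 for B cells, 0.943 for neutrophils, 0.537 for mitochondrially encoded genes and 0.78 for ribosomal protein genes by exact permutation. The natural killer sum averaged 383 TPM in control libraries, where Gzma, Eomes, Xcl1 and Il2rb held 2.98, 1.56, 4.19 and 9.67 TPM. It was highest, at 651, in control replicate 3, which also had the highest macrophage sum. Most of it came from other members of the list, so its flat value does not settle the share of natural killer cells.

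Genes of the cell division cycle were lower in the treated libraries. Ube2c and Cdc20, which drive the destruction of mitotic regulators, and Plk1, a mitotic kinase, fell by 1.38, 1.24 and 1.23. Ube2c went from 32.7 ± 7.77 TPM (SD, n = 4) to 12.3 ± 4.29 TPM (SD, n = 3). Of 32 cell cycle genes 16 fell and 0 rose (median -0.73), and 22 fell when adjusted over the list alone. Mki67, a proliferation marker, had a log2 fold change of -0.27 (limma, Benjamini-Hochberg adjusted p = 0.504). Camera with a preset correlation gave a Benjamini-Hochberg adjusted p of 3.58e-06, with adjusted p = 0.695 with an estimated correlation. Without the third treated library 10 of the 32 were called lower, and without it and control replicate 3, a choice made after the data were seen, 4 were. The median was -0.48 and Cdc20 at -0.78 with array weights, and Plk1 was at -0.78 with a pseudocount of 5. The 15 tested epithelium and mesothelium genes, of which 9 fell, had a median of -0.76 in the same libraries.

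Lists of energy metabolism genes had medians below 0, as the median of all tested genes was, and few members passed the test. Over all 14967 tested genes 1136 were called lower. Hk2, Tpi1 and Pgk1, glycolytic enzymes, fell by 0.86, 0.77 and 0.75 and were the 3 of 20 glycolysis genes that passed (median -0.57, and 12 lower when adjusted over the list alone). Of 37 oxidative phosphorylation genes 1, Sdhc, fell (median -0.37, and 0 when adjusted over the list alone). Of 18 tricarboxylic acid cycle genes 1, Pcx, fell (median -0.32, 1 when adjusted over the list alone). Of 21 fatty acid oxidation genes 2, Ppard and Cpt2, fell (median -0.39, 2 when adjusted over the list alone). Cpt1a, the gate enzyme of fatty acid oxidation, had a log2 fold change of -0.18 (limma, Benjamini-Hochberg adjusted p = 0.537). Camera with a preset correlation called these 4 lists down (Benjamini-Hochberg adjusted p = 0.0173, 0.00369, 0.038 and 0.0165), with adjusted p = 0.818 for each with an estimated correlation. The median gene of all those tested had a log2 fold change of -0.244, and relative to it the 4 medians were -0.32, -0.12, -0.08 and -0.15. Summed epithelium and macrophage markers were 0.501-fold and 0.517-fold the control level in the same libraries, where the T cell identity median was 2.81. The macrophage sum was mostly Apoe in control libraries, 5056 of 8948 TPM, and neither sum passed the exact permutation test (Benjamini-Hochberg adjusted p = 0.0619 each). Without the third treated library, which had 32.87% of its TPM in mitochondrially encoded genes, the oxidative phosphorylation median was -0.16 and the tricarboxylic acid cycle median -0.12. Camera no longer called the tricarboxylic acid cycle without any of the 4 control replicates (adjusted p from 0.0533 to 0.113), glycolysis without control replicate 2 or 3 or treated replicate 1 (0.0893, 0.062 and 0.0702), oxidative phosphorylation without control replicate 2 (0.0812), or fatty acid oxidation without control or treated replicate 2 (0.108 and 0.125). Quantile normalization also ended the calls of oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation (medians -0.06, -0.10 and -0.15, camera adjusted p = 0.284, 0.285 and 0.187) and put Tpi1 at -0.40. Requiring a TPM of at least 5 ended the calls of glycolysis, the tricarboxylic acid cycle and fatty acid oxidation (0.0536, 0.198 and 0.0536). Array weights and the macrophage covariate ended those of glycolysis (0.169 and 0.0507) and the tricarboxylic acid cycle (0.0773 and 0.056), which other variance models ended too (0.0529 and 0.0561). With median-of-ratios scaling the 4 medians were -0.32, -0.12, -0.07 and -0.15, 1 glycolysis gene fell, Hk2, and 1 rose, Slc2a3, and Tpi1, Pgk1, Sdhc and Cpt2 were not called (limma, Benjamini-Hochberg adjusted p = 0.0522, 0.0827, 0.0534 and 0.0737). Of the single genes, Tpi1, Pgk1, Sdhc, Pcx, Ppard and Cpt2 each lost the limma call without control replicate 2 (Benjamini-Hochberg adjusted p from 0.0676 to 0.131) and without at least 1 other library. Of 23 genes of cholesterol and fatty acid synthesis 0 passed by either adjustment (median -0.38, and camera adjusted p = 0.283, or 0.0157 with no filter).

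Genes that sense, carry or use short-chain fatty acids showed little difference. Acss1, a mitochondrial enzyme that activates acetate, rose by 1.27 (SE 0.30) from 1.98 ± 0.502 TPM (SD, n = 4) to 6.65 ± 3.63 TPM (SD, n = 3). The change was 0.70 with a pseudocount of 5, and without treated replicate 2 it was 0.92 (limma, Benjamini-Hochberg adjusted p = 0.0525). It was the 1 of 15 tested members that passed (median -0.27, 1 when adjusted over the list alone, and camera adjusted p = 0.98), and Bdh1 rose as well with median-of-ratios scaling. Slc16a1, a transporter of short-chain fatty acids and lactate, had a log2 fold change of -0.49 (limma, Benjamini-Hochberg adjusted p = 0.123). Ffar2, a receptor for these acids, stayed below the filter at 0.4 ± 0.18 TPM (SD, n = 4) in control and 0.38 ± 0.292 TPM (SD, n = 3) in treated libraries. Of 25 genes of histone deacetylases, only some of which butyrate inhibits, and of acetyltransferases, 0 passed by either adjustment (median -0.13, which turned to 0.09 with median-of-ratios scaling, and camera adjusted p = 0.753). With that scaling Sirt1 and Kat6a rose by 0.55 and 0.54 and Hdac10 fell by 0.37 (limma, Benjamini-Hochberg adjusted p = 0.0353, 0.0137 and 0.0498).

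Few stress and interferon genes passed the test. Of 24 immediate early and stress genes, Dusp2, a phosphatase of activated lymphocytes, and Klf6 rose by 2.41 and 0.89 and 0 fell (median 0.13, 1 higher when adjusted over the list alone). The camera adjusted p was 0.00095, with adjusted p = 0.695 with an estimated correlation. Of 30 type I interferon response genes, Ifi213 and Ifi203 (the latter named after its value was seen) rose and Oasl1 and Oas2 fell (median -0.20, with 2 higher and 3 lower when adjusted over the list alone). Camera gave that list an adjusted p of 0.717 with the direction up, opposite to its median, and the median turned to 0.02 with median-of-ratios scaling. Of 23 genes of the interferon gamma response and class I presentation, 1 rose, Nlrc5, the transactivator of class I genes (median 0.17, 1 when adjusted over the list alone). The camera adjusted p was 0.00023, with adjusted p = 0.695 with an estimated correlation. Of 18 p53 and apoptosis genes, Pmaip1 rose by 1.28 and Cdkn1a and Phlda3 fell by 1.12 and 1.51 (median -0.28). When adjusted over the list alone, 1 rose and 3 fell, and the camera adjusted p was 0.753. Of 19 mTORC1 and amino acid response genes, Slc1a5, a glutamine transporter, rose by 0.96, and Eif4ebp1, Asns, Sesn2 and Psat1 (the last pair named after their values were seen) fell (median -0.24, which turned to 0.01 with median-of-ratios scaling). When adjusted over the list alone, 2 rose and 4 fell, and the camera adjusted p was 0.659. The immediate early median was 0.08, 0.01 and 0.38 without control replicates 1, 2 and 3, and the list was not called without the third treated library (median 0.19, camera adjusted p = 0.0985). With median-of-ratios scaling the immediate early and interferon gamma medians were 0.39 and 0.42, Gbp4, Psmb9, Bcl2l11 and Sesn3 were among those that rose, Ifi44 and Bcl2l1 fell, and Oas2, Cdkn1a and Pmaip1 were not called (limma, Benjamini-Hochberg adjusted p = 0.141, 0.0564 and 0.059). Robust variance estimation ended the limma calls of Ifi213, Nlrc5 and Pmaip1 (Benjamini-Hochberg adjusted p = 0.0907, 0.062 and 0.157), and a pseudocount of 5 those of Klf6 and Oas2 (0.056 and 0.052). Slc1a5 was at 1.54 with array weights. The interferon gamma median was 0.29 and 0.10 without control replicates 1 and 4, 0.38 without the third treated library and -0.10 without treated replicate 2. Leaving out treated replicate 2 also ended the limma calls of Nlrc5, Slc1a5, Klf6 and Pmaip1 (0.82, 0.59, 0.65 and 1.04, Benjamini-Hochberg adjusted p from 0.0625 to 0.16), and those of Slc1a5, Klf6, Pmaip1 and Oas2 were lost without some of the other libraries as well.

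**Figure D3:**
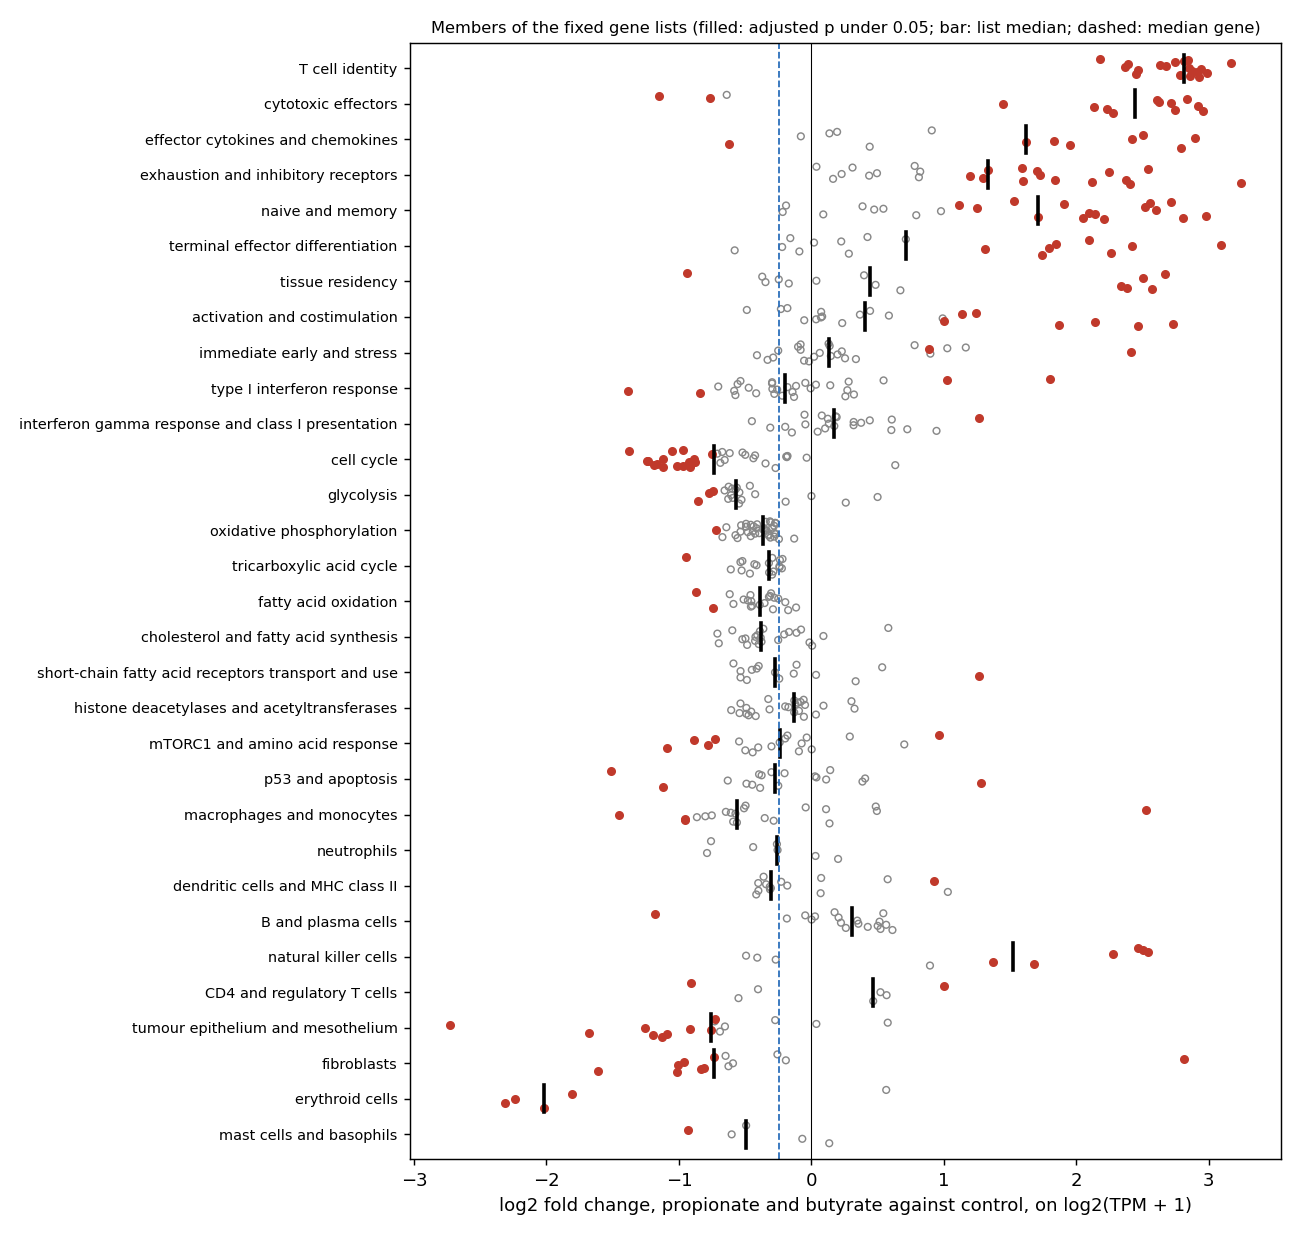
Log2 fold changes, propionate and butyrate against control on log2(TPM + 1), of the tested members of 31 fixed gene lists. Each point is a gene, filled where its adjusted p was under 0.05, short bars are list medians and the dashed line is the median of all tested genes at -0.244. The T cell identity list has 19 of 19 members filled and a median of 2.81, and the cell cycle list has 16 of 32 filled, each of them below 0.

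Over all 14967 tested genes, limma with Benjamini-Hochberg adjustment called 1779 genes, 643 higher and 1136 lower in the treated libraries. With median-of-ratios scaling, which moved the median gene from -0.244 to -0.022, the split was 1234 higher and 993 lower, with 624 higher and 856 lower genes called under both. Relative to the median gene the T cell identity, cell cycle and epithelium medians were 3.05, -0.49 and -0.51. Of the called genes, 1688 had no overlap between the groups' libraries, as did 30.55% of all tested genes against 5.71% by chance. The genes selected as the largest rises were Ctla4, Trbc1, Klrc1, Cd8a, Ms4a4b, Il7r, Gzmb, Lat, Cd3e and Rgs16. The largest falls included Sprr1a, Rbp2, Cldn3, Rn7sk, Mmp10, Bace2, Chst1, Hba-a2 and Cxcl17, from -3.01 (Sprr1a) to -2.28 (Cxcl17). Sizes and order rested on the pseudocount: with a pseudocount of 5 Ctla4 was at 2.00 and Trbc1 at 2.82, and Sprr1a, Rbp2, Cldn3, Mmp10, Bace2 and Chst1 were at -1.87, -1.64, -1.41, -1.47, -1.02 and -1.17, Bace2 being at -4.30 with a pseudocount of 0.1. Rn7sk is a small RNA without a poly(A) tail whose control values spread widely (181 ± 174 TPM, SD, n = 4), and it was not called without the third treated library or with robust variance estimation (limma, Benjamini-Hochberg adjusted p = 0.056 and 0.0881). A further 97 higher and 97 lower genes carried only model numbers as names, and 52 of the genes that rose and 4 that fell were T cell receptor or immunoglobulin segments. With no filter on low values limma called 7 genes at an adjusted p under 0.05, 6003 having an unadjusted p under 0.05, and 0 of the 19 T cell identity genes passed. Leaving out a library gave 974 (treated replicate 2) to 3363 (treated replicate 1) calls. With the T cell identity level as a covariate, chosen after the data were seen, 4 genes were called (2267 had an unadjusted p under 0.05). With an estimated correlation, 0 of the 20 lists past the preset camera test were called.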

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

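All tests of explanations in this part were chosen after the results they bear on were seen. Among 131 sets of control values, 9 had a library far from the other 3, and chance gives about 6.6. Control replicate 3 held 4 of them, with 8468 TPM of Apoe, a macrophage gene, where the others had 3741 to 4121, 15513 summed TPM of macrophage and monocyte markers against 6474 to 7326, 49.2 TPM of Cd44 against 26.7 to 27.5, and 9.09 TPM of Mmp9, a neutrophil and macrophage protease, against 1.53 to 1.85. Control replicate 2 stood out with 20.33 TPM of Cldn3, 44.28 TPM of Ube2c, 8.65 TPM of Pcx and 888.5 TPM of Krt19, where the other controls had at most 8.57, 29.74, 5.34 and 634. Control replicate 4 had 27.24 TPM of Fasn, the fatty acid synthase gene, against 41.4 to 43.7 in the others.

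The first pattern weighed was the rise of T cell genes in the treated libraries. The scaling of TPM and the mitochondrial share are argued against as the whole cause, since at least 19 of 19 T cell identity genes were called under each of 3 other scalings, and so is dependence on a given library, since at least 19 of 19 were called whichever of the 7 was left out. The 19 genes rose by 2.43 to 3.27 in log2 TPM, with a median of 2.98, so most of the rise was shared by all of them. A larger share of T cell RNA would raise them alike. The SD between them was 0.24, against a median standard error of 0.15 for a gene relative to each library's list mean. These 2 values bear only on the smaller differences around the shared rise. They cannot tell whether single genes changed on top of it. A first comparison used the whole standard error, 0.33, and was set aside because most of it is spread the genes share. Whether the rise follows the treatment or the purity of the cell isolation cannot be told apart, since the lowest treated sum was 2.78 times the highest control sum and the labels give no purity for either group. A change in T cell number with the treatment stays open as well.

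The second pattern was the rise of effector, checkpoint and memory genes. Relative to the mean of the T cell identity genes, the lists of cytotoxic effectors, cytokines and chemokines, and exhaustion differed by -0.90, -1.36 and -1.19 on the log2 scale (two-sided exact permutation p = 0.0571 each), and those of naive and memory and of terminal effector genes by -1.13 and -1.63 (p = 0.0286 each), with a Benjamini-Hochberg adjusted p of 0.0571 for each of the 5. Of 13 such genes 0 passed the same exact permutation test (smallest Benjamini-Hochberg adjusted p 0.248), with Gzmb, Ifng and Pdcd1 at 0.49, 0.26 and -0.23, Tnf and Havcr2 at -2.32 and -1.11, and Tcf7 at -0.65 with the only unadjusted p under 0.05, 0.0286. An earlier limma test of the same ratios called 1 of the 13, Tnf (Benjamini-Hochberg adjusted p = 0.000761), and was set aside after that result was seen because it pooled the variance of 14588 ratios that share the same divisor, giving 72940 degrees of freedom. A larger T cell share alone and a change within the T cells therefore cannot be told apart, because 35 splits leave little power and other cells also express members of these lists, such as Tnf, Havcr2 and Csf1.

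The third pattern was the fall of cell cycle genes. The scaling of TPM is argued against as the whole cause, since at least 14 of 32 genes were called lower under each of 3 other scalings. Dependence on given libraries is not argued against. Without the third treated library 10 of the 32 were called lower, and without it and control replicate 3 only 4 were, at medians of -0.56 and -0.54. Relative to the mean of the epithelium and mesothelium list, the cell cycle mean differed by 0.17 between the groups, within the pooled SD of 0.261 (exact permutation p = 0.543). A smaller share of dividing tumour epithelial or mesothelial cells thus stays possible, but this value does not single it out. No other cell list was set against the cell cycle genes, and the fibroblast median of -0.74 was also near the cell cycle median of -0.73. Of the most abundant epithelium and mesothelium markers, Krt19, Krt8 and Krt18 fell, from 680, 362 and 361 TPM to 218, 161 and 173. Wt1 had a log2 fold change of -0.69 from 502 TPM (limma, Benjamini-Hochberg adjusted p = 0.0574, or 0.0455 with median-of-ratios scaling). A change in division within the T cells stays open.

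Whether chance could give as many called genes was tested by regrouping the libraries. Of 35 splits into 4 and 3, 1, the real split, gave as many genes, with 1779 against at most 5 in any other. This is a share of 0.0286, the smallest that 35 splits allow. Every other split mixed treated and control libraries within a group, which widens the spread there and holds the count down. The number of genes therefore set the real split apart from the others, but this test cannot exclude chance. For the number of lists past the preset camera test, 5 of 35 splits, the real one with 20 included, gave as many, the highest of the others giving 22, so chance could not be excluded.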

How the results depend on the processing

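The alternatives were chosen before the data were examined, except the T cell identity level as a covariate and the removal of control replicate 3 together with the third treated library, chosen after. All 19 T cell identity genes were called higher under each setting except no filter on low values and the T cell identity covariate, where 0 were, in the latter because the list was adjusted for itself. Over settings that left no library out, 1290 comparisons of named genes kept their direction and side of the threshold, 236 lost the call, 50 gained it and 32 turned; of those of lists, 403 kept, 66 lost, 3 gained and 20 turned. The direction of a list is here the sign of its median, and for lists past the threshold also that of camera. Depth is unknown, so no limit from it can be given.

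Against 1779 genes called (643 higher, 1136 lower), no filter on low values gave 7 (3 higher, 4 lower, and 6003 with an unadjusted p under 0.05), with 29687 genes tested and the median degrees of freedom at 7.4 in place of 14.6. Array weights gave 6467 (2246 and 4221), median-of-ratios scaling 1234 higher and 993 lower, and quantile normalization 1159 higher and 1292 lower. The T cell identity covariate, whose values do not overlap between the groups, gave 4 (1 and 3, with 2267 at an unadjusted p under 0.05). Median-of-ratios scaling, with median degrees of freedom of 8.1, called 2227 genes in total. For the filter, the other scalings and the weights the cause of the change in counts was not tested. By construction, a minimum of 2-fold gave 929 (586 and 343), an adjusted p under 0.1 gave 3124 (832 and 2292), and an unadjusted p under 0.05 with a minimum of 2-fold gave 1007 (638 and 369). Without control replicate 3 and the third treated library 855 were called (588 and 267).

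Leaving out a library gave 974 to 3363 genes (855 with 2 removed), 388 to 794 higher and 585 to 2909 lower (267 with 2 removed). The total was 1159 without control replicate 2, 974 without treated replicate 2 and 3363 without treated replicate 1, and the lower genes were 694, 585 and 730 without control replicates 1, 2 and 3, 2909 and 586 without treated replicates 1 and 2, and 610 without the third treated library.

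Of 31 lists, 20 were past the preset camera test, 15 to 21 under the other settings, and 0 with an estimated correlation (smallest adjusted p 0.23) or by fry (smallest adjusted p 0.0652). For the summed TPM of other-cell lists 0 of 13 tests passed in the 3 versions tested, which says nothing about stability, since the smallest exact permutation p of 0.0286 gave an adjusted p of 0.0619 even with 6 sums fully apart.

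The labels give numbers 1 to 3 in both groups, but the column of the third treated library could not be matched to one, so only numbers 1 and 2 could be compared. Samples with these numbers did not deviate together (correlations across genes of -0.02 and -0.09). Treated replicates 1 and 2 gave -0.23 to 0.17 with controls of other numbers. So few values within that spread cannot show whether equal numbers mark a pairing. The third treated library correlated best with control replicate 3, at 0.19, and treated replicates 1 and 2 with control replicates 2 and 3, at 0.17 and 0.04. With the replicate block as a fixed factor 705 genes were called (565 higher, 140 lower). That fit takes the group difference only from the libraries numbered 1 and 2 in both groups, and the other libraries do not enter it. Its count and fold changes are therefore not a result of all libraries. With the replicate block as a random effect 1243 genes were called (506 higher, 737 lower), the consensus correlation being -0.259. Under the fixed block the histone deacetylase median turned to 0.04 and Mki67 to 0.03, and under the random block Cd44 to -0.01.

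With the T cell identity covariate these turned: Cd8a -0.03, Ms4a4b -0.08, Tigit -0.01, Satb1 -0.17, Cd27 -0.32, Tnfrsf9 -0.07, Il2rb -0.65, Nlrc5 -0.51, Gbp4 -0.74, Psmb9 -0.44, Acss1 -0.34, Slc1a5 -0.57, Ly6c2 -0.43, Siglech -0.40, Tnfrsf18 -0.58, Thy1 -0.04, Cd8b1 -0.25, Prf1 -0.54, Pdcd1 -0.85, Havcr2 -0.35, Lag3 -0.52, Tox -0.21, Tcf7 -0.79, Cd44 -0.16, Mmp9 0.23 and Csf3r 0.84. The covariate is the level of the T cell identity list, so the values near 0 of that list and its members were fixed by construction and say nothing about stability. The list medians turned for T cell identity (-0.04), cytotoxic effectors (-0.06), exhaustion and inhibitory receptors (-0.08), naive and memory (-0.46), tissue residency (-0.04), activation and costimulation (-0.20), interferon gamma response and class I presentation (-0.80), macrophages and monocytes (0.25), neutrophils (0.91), B and plasma cells (-0.05) and CD4 and regulatory T cells (-0.66), and camera's direction for fibroblasts (median -0.49) and erythroid cells (median -0.91).

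Elsewhere the cause was not tested. With median-of-ratios scaling the list medians of type I interferon response, histone deacetylases and acetyltransferases and mTORC1 and amino acid response turned to 0.02, 0.09 and 0.01, and Cpt1a to 0.08 (0.13 with quantile normalization). The histone deacetylase median was 0.02 without mitochondrial, ribosomal protein and receptor segment genes and 0.03 without 2 libraries. With array weights the type I interferon median was 0.05 and Mki67 0.12, and without 2 libraries these were 0.08 and 0.04. With the macrophage covariate the neutrophil list had a median of 0.31 and Csf3r 0.02. The mean of log2(TPM + 1) gave 0.18 for CD4 and regulatory T cells. Leaving out libraries moved the list medians of type I interferon response from -0.32 to 0.08, interferon gamma response and class I presentation from -0.10 to 0.40, histone deacetylases and acetyltransferases from -0.26 to 0.03, neutrophils from -0.68 to 0.20 and CD4 and regulatory T cells from -0.04 to 0.49, and Cd44 from -0.13 to 0.32 and Mki67 from -0.56 to 0.04.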

Other observations

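The families below were chosen after the data were seen and their members vary together, so no p-value is given for the number of members called. The p-values given below are for summed segments per library and carry the same late choice. Gimap genes, GTPases of lymphocytes that support their survival, were higher throughout, with 9 of 9 tested members called and a median log2 fold change of 2.58. Killer cell lectin-like receptor genes rose in 9 of 16 members. Of variable segments of the T cell receptor, 19 of 20 beta segments and 29 of 35 alpha segments rose, and their summed TPM went from 47.2 ± 13.9 (SD, n = 4) to 493 ± 319 (SD, n = 3) and from 25.5 ± 9.67 (SD, n = 4) to 279 ± 184 (SD, n = 3), each with an exact permutation p of 0.0286 and 0.0572 after Benjamini-Hochberg adjustment over 4 sums. Variable segments of the immunoglobulin heavy and kappa chains, from B cells, differed by 0.26 and 0.37 on the log2 scale (exact permutation p = 0.83 and 0.66). Reads of near-identical segments can be split between copies, so single segments are uncertain. Testing needed a TPM of at least 1 in at least 3 libraries, the size of the treated group. Low segments that were high only there could thus enter, which favours the shares that rose.

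Keratin genes fell in 5 of 9 members (median -1.09) and claudin genes in 2 of 3. Of 130 ribosomal protein genes 6 rose and 1 fell, and of 15 mitochondrially encoded genes 0 passed. Ptprc, the pan-leukocyte gene CD45, went from 35.3 ± 15.6 TPM (SD, n = 4) to 162 ± 91.8 TPM (SD, n = 3), a log2 fold change of 2.13, and Cd4 from 0.878 ± 0.418 TPM (SD, n = 4) to 1.61 ± 0.689 TPM (SD, n = 3), which did not pass (limma, Benjamini-Hochberg adjusted p = 0.25). In the control libraries, labelled as CD8+ T cells, Apoe at 5056 TPM, Wt1, a mesothelial gene, at 502 TPM and Krt8 at 362 TPM stood above Cd8a at 14.1 TPM.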
